A study of Homo sapiens with 8 samples.

How the data were processed

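RNA of 22Rv1 cells was measured on 8 single-colour (Cy3) Agilent expression arrays, all on 1 slide. 22Rv1 is an established human prostate cancer cell line derived from a xenograft that had relapsed after castration of the host mice. The arrays hold 3 groups: the parental line (2 arrays), a Cas9 control line transfected with the PX459 plasmid, which carries Cas9 and a puromycin resistance gene (2 arrays), and 4 NCOA6 knockout clones (1 array each, clones 2-74 and 2-96 of series 2 and clones 4-91 and 4-105 of series 4). Per the labels, guides against an exon of NCOA6 were delivered transiently, cells were selected with 5 µg/ml puromycin for 2 days, and clones were picked and checked by PCR, sequencing and Western blot. RNA was taken 24 hours after passage and 50 ng was labelled per array. The labels do not say which clone series (names starting with 2 or 4) goes with which targeted exon, whether the control line grew from a single cell, or whether replicates of a line were separate cultures. Where nothing says that replicates were separate cultures, p-values measure only the spread between these samples.

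The scanner files hold intensity values per the file headers, made with Agilent Feature Extraction 11.0.1.1, which subtracts background and a spatial trend within each array, replaces the smallest values by a surrogate above 0, and applies no scaling between arrays. The deposited series table holds log2 values for 52731 probes, from 4.02 to 17.98, whose array medians lie between 5.09 and 5.10. The submitters' processing notes name limma without a version or a step. That table has no value for the NCOA6 probe, so the scanner values were used for the main results and the deposited log2 values as an alternative. For the same array, the log2 values of both sources correlated across probes with r between 0.993 and 0.996, with slopes between 0.891 and 0.906 (across genes, which are not independent replicates).

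Each array has 62976 spots, of which 2075 are controls and 60901 carry 58201 probes. Spots marked as outliers by the scanner software (787 over all arrays) were left out, no spot was saturated (0), and the 138 probes without a value on some array were dropped. Values are log2 of the processed intensity minus the log2 of the array's 75th percentile, so a level of 0 is the 75th percentile of that array. A probe was tested when it was well above background on at least 2 of 8 arrays (24624 probes). Probes were named through their transcript accession and the RefSeq gene names. This gave a gene for 31104 of 58201 probes (53.4%) and none for 27097. Each gene was represented by the probe with the highest mean over all 8 arrays, which gave 19858 features, 14183 with a gene name (12660 of them protein-coding) and 5675 probes without one. The probes were placed on an older genome build than these gene records, so no coordinates are given, and the position of the NCOA6 probe relative to the edited exons was not determined. Chromosome and gene order come from the gene records.

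Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (version 1.17.8). Calls are at a Benjamini-Hochberg adjusted p under 0.05. The tests are two-sided. NCOA6 itself was also tested with an exact permutation test. Knockout and wild type (parental and Cas9 control together) were fitted as 2 groups, and the other comparisons in fits with 3 groups that share 1 estimate of the spread. These comparisons, the tests, the rule for naming genes, 40 gene lists and most alternatives were chosen before the data were examined. A list was tested when at least 3 of its genes were measured (39 lists; the 10 endothelial markers had 0 tested genes). Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the lists. In fry, the directional p tests whether a list's genes move one way on balance, and the mixed p whether they change in either direction. The lists are from textbook knowledge and were not chosen on these samples.

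The rule for naming genes took NCOA6, and for knockout against wild type the 12 largest rises and 12 largest falls among protein-coding genes with an adjusted p under 0.05 in which every clone lay beyond every wild-type array. It added, from each list that passed its test or held at least 3 called genes, up to 4 members with the smallest adjusted p. For each other comparison it took the 5 largest rises and 5 largest falls, or the 3 smallest p where none passed. Other genes are named only where a value of a list member or a count of 5 or fewer called for it, and these were chosen after their values were seen. Y-linked genes and XIST were left out. Where no probe of a gene was well above background on any array of a group, its fold is given as a lower bound. The bound sets the arrays below background to the lowest level that counted as well above background on that array, or to the gene's own value where that was higher. Where only some arrays of the lower group were above background, the others were set in the same way, a rule chosen after the values were seen. List medians use the fitted differences, and where genes at a bound change a median it is also given with those genes at their bounds.

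The number of arrays limits the precision: 4 against 4 arrays leave 6 residual degrees of freedom and comparisons with 3 groups leave 5. The procedure was tested on simulated data with 200 of 19858 genes changed. The tests on dim genes depend on the background, which is why the filter was varied. Alternatives were: normexp background correction (offset 50), for which the median spot signal was used because the files lack the mean spot signal, quantile normalization, median centring, cyclic loess, the series table, filters at 4 or 8 arrays or none, the mean of a gene's probes, a trended robust prior, array weights, averaging or blocking the wild-type lines, fits on fewer arrays, stricter thresholds, other list tests, and leaving out each array in turn. Centring each gene on its chromosomal neighbours and leaving out whole chromosomes were added after the data were seen. A replicate number does not pair arrays of both wild-type lines as far as the values show: the difference between replicates correlated across genes with r = 0.0848 between the 2 lines.

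Wild-type arrays lay in slide row 1 and knockout arrays in slide row 2, so row and genotype cannot be told apart by the design.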

Results

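Gene expression was measured in 22Rv1 prostate cancer cells with and without NCOA6, a coactivator of nuclear receptors that is also a subunit of the MLL3 and MLL4 histone methyltransferase complexes. The series asks which genes NCOA6 influences in these cells. The parental line (2 arrays) and the Cas9 control line (2 arrays) were wild type for NCOA6, and 4 clones were knockouts. The 75th percentile of the probe intensity was 85.5 and 99.97 in the parental replicates, 91.9 and 102 in the control replicates, 77.5 in clone 2-74, 80.5 in clone 2-96, 82.6 in clone 4-91 and 80.2 in clone 4-105. Between 39.9% and 41.1% of probes were well above background on wild-type arrays and between 37.0% and 38.8% on knockout arrays. The median SD of a gene was 0.101 within the wild-type lines and 0.178 among the clones, on the log2 scale.

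NCOA6 mRNA was lower in every clone than on every wild-type array. Its probe (A_23_P259135, the only NCOA6 probe on the array) had a log2 level of 2.24 ± 0.37 (SD, n = 4) in the clones and 3.75 ± 0.04 (SD, n = 4) in wild type, a difference of -1.51 (SE 0.17, adjusted p = 0.000364) or 2.85-fold. The clones kept 34.9% (2-74), 33.2% (2-96), 49.2% (4-91) and 26.5% (4-105) of the mean wild-type signal. An exact two-sided permutation test gave p = 0.0286, the smallest that 70 arrangements allow. The control and parental lines differed by 0.07 (adjusted p = 1), and the clone series by 0.08 (adjusted p = 0.936). A transcript that remains measurable does not speak for or against loss of the protein, and where the probe lies relative to the edited exons was not determined.

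Knockout clones lost the signal of several genes whose level in wild-type cells was well above the array's 75th percentile. SPINK1, a secreted trypsin inhibitor, had a level of 7.84 ± 0.09 in wild type and was below background in all 4 clones, at least 1261-fold lower (adjusted p = 1.14e-07). AKR1C3, an aldo-keto reductase that makes testosterone from androstenedione, was at least 257-fold lower (5.54 ± 0.04 in wild type, below background in all 4 clones, adjusted p = 1.46e-09). VIL1, which encodes the microvillus protein villin, was at least 88.4-fold lower, and STAT6, the transcription factor of interleukin-4 signalling, at least 89.3-fold lower. The glycosyltransferase gene B3GNT3 (at least 46.8-fold), the tight-junction gene CLDN11 (at least 46.9-fold), the engulfment adaptor gene GULP1 (at least 97.4-fold) and DDC, the aromatic amino acid decarboxylase gene (at least 42.5-fold), were also below background in every clone. A second probe of GULP1 differed by less, -4.61. TSPAN8 (a tetraspanin), AMER3 and KLK11 (a kallikrein-related peptidase) were at least 185-fold, 160-fold and 59.6-fold lower, with 1 clone above background for each. MYO1A, a brush-border myosin, was at least 77.2-fold lower with 2 clones above background.

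Other genes rose in the clones. VWA2, which encodes a secreted protein with von Willebrand factor domains, rose 16.7-fold, from -1.81 ± 0.21 to 2.25 ± 0.30 (SD, n = 4 each, adjusted p = 1.72e-06). CPS1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, rose 14.4-fold (adjusted p = 9.47e-07). TBX1, a T-box transcription factor, rose 10.9-fold, from 0.66 ± 0.07 to 4.10 ± 0.24 (adjusted p = 6.22e-07). Below background in wild type and above it in all 4 clones were the membrane protein gene FLRT2 (at least 12.4-fold higher), the WNT inhibitor gene APCDD1 (at least 10.8-fold), the homeobox gene GSC (at least 8.21-fold), CHN1, a regulator of Rac (at least 7.18-fold), the contactin gene CNTN3 (at least 6.97-fold) and the surface protein gene CD83 (at least 5.11-fold). The homeobox gene BARX1 (at least 2.73-fold), the endothelin receptor gene EDNRA (at least 3.10-fold, adjusted p = 0.0187) and the collagen VI gene COL6A2 (at least 2.78-fold, adjusted p = 0.000836) were above background in 3 of 4 clones. A second COL6A2 probe was above background in wild type and differed by 1.32. EDNRA lost its call when each wild-type line was averaged first (adjusted p = 0.112, range over the alternatives 3.05e-06 to 0.112).

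**Figure D1:**
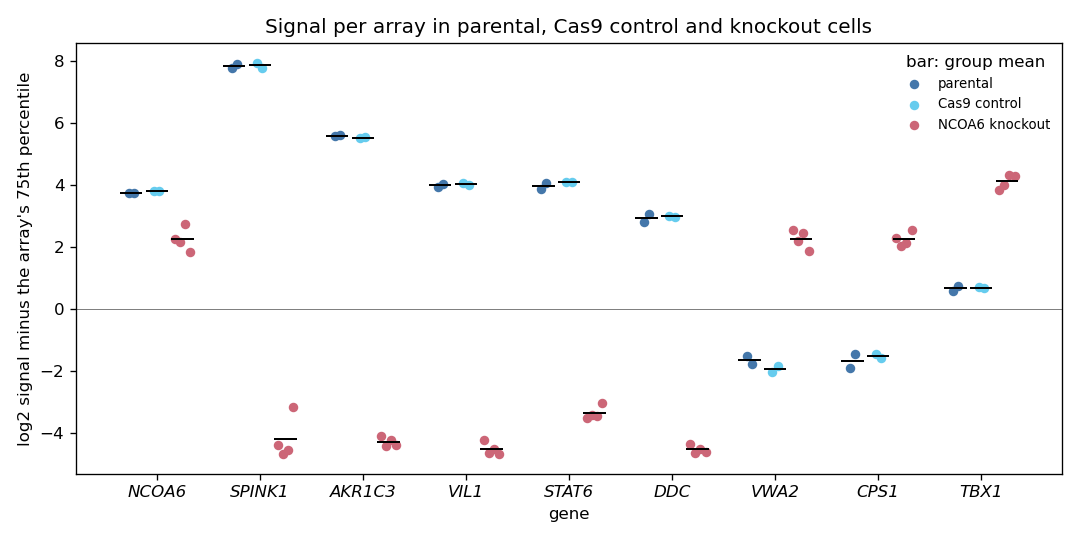
Log2 level (y axis, relative to the 75th percentile of the array) of 9 genes on each of the 8 arrays, 1 gene per position on the x axis; points are arrays, bars are group means. NCOA6 was 2.24 on average in the 4 clones and 3.75 on the 4 wild-type arrays, and SPINK1 was below background in every clone at a wild-type mean of 7.84.

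In all, 8413 of 19858 features (42.4%) differed between knockout and wild type by limma, 4190 higher and 4223 lower in the clones. With arrays below background held at the lowest measured level, 705 were at least 2-fold higher and 1125 lower, and 15 at least 8-fold higher and 178 lower. All 4 clones lay beyond all 4 wild-type arrays for 44.3% of features, where chance gives 2.86% for independent arrays. These arrays were not known to be independent: wild type was 2 lines in duplicate, and the 4 clones may share an ancestor. Averaging each wild-type line first, so that 2 lines stood against 4 clones, left 4894 calls, and all knockout arrays lay in a slide row of their own.

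Genes that androgens repress, as listed from textbook knowledge, were lower in the clones. Of 10 measured members 7 fell and 0 rose (0 rose and 8 fell when adjusted over the list alone), with a median of -2.59 and adjusted p = 1.79e-05 (adjusted p = 0.22 with an estimated correlation). They included DDC, the steroid glucuronidation genes UGT2B15 (at least 25.8-fold lower) and UGT2B7 (at least 2.31-fold lower), and MET, the hepatocyte growth factor receptor gene, which fell 13.2-fold (adjusted p = 9.74e-08). With the 5 members below background in the clones held at their bounds, the median was -0.94. When only features above background on all 8 arrays were tested, which removes the members that fell to background, the median was -0.21 and the call ended (adjusted p = 0.143, range over the alternatives 5.52e-07 to 0.22).

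Neuroendocrine and neuronal markers fell as well: 10 of 13 were lower and 1 was higher (10 lower and 2 higher adjusted over the list alone), with a median of -2.85 and adjusted p = 0.000429 (adjusted p = 0.239 with an estimated correlation). CHGA, which encodes chromogranin A of secretory granules, was at least 21.1-fold lower, the stem-cell factor SOX2 at least 1.44-fold lower, and the neural factor POU3F2 at least 7.19-fold lower with 1 clone above background. DLL3, a NOTCH ligand gene, rose by 1.81 (adjusted p = 1.93e-05). With 4 members at their bounds the median was -1.91. Restricting the test to features above background on all 8 arrays ended this call too (adjusted p = 0.263, range over the alternatives 2.57e-06 to 0.263).

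HOX genes, which set positional identity and are classical polycomb targets, fell in 13 of 18 cases and rose in 0 (14 and 0 adjusted over the list alone). Their median was -2.12 and adjusted p = 1.8e-05 (adjusted p = 0.29 with an estimated correlation), or -1.68 with 5 members at their bounds. HOXB8 was at least 8.81-fold lower, HOXC10 at least 2.92-fold, HOXA13 at least 1.44-fold, and HOXA7 at least 12-fold with 3 clones above background. HOXB13, the prostate HOX gene, differed by 0.09 (adjusted p = 0.519).

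Targets of the liver X receptor, a sterol sensor, were lower in 7 of 8 cases (7 lower and 0 higher adjusted over the list alone), with a median of -0.92 and adjusted p = 0.000881 (adjusted p = 0.22 with an estimated correlation). The phosphodiesterase gene SMPDL3A fell 7.37-fold (adjusted p = 1.32e-07), MYLIP, which encodes a ligase that degrades the LDL receptor, fell by 1.06, the desaturase gene SCD by 0.50 and SREBF1, a master regulator of fatty acid synthesis, by 0.79. SREBF1 lost its call when each wild-type line was averaged first (adjusted p = 0.0587, range over the alternatives 0.000598 to 0.0587), its second probe differed by -0.01, and with 1 member at its bound the list median was -0.65. TGF-beta and BMP targets changed in 8 of 8 cases, 7 of them lower (7 lower and 1 higher adjusted over the list alone), with a median of -1.01 and adjusted p = 0.00601 (adjusted p = 0.252 with an estimated correlation). INHBA, an activin subunit gene, was at least 2.51-fold lower, the inhibitory SMAD gene SMAD6 fell by 1.05 and ID2, an inhibitor of basic helix-loop-helix factors, by 3.10. PMEPA1, which restrains TGF-beta signalling, rose by 1.07.

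Luminal epithelial markers of the prostate fell in 10 of 19 cases and rose in 2 (10 lower and 3 higher adjusted over the list alone), with a median of -0.55 and adjusted p = 0.0136 (adjusted p = 0.252 with an estimated correlation). The members that fell included the tight-junction gene CLDN3 (13.4-fold), the keratins KRT18 (by 1.07 on the log2 scale) and KRT8 (by 1.83; its second probe differed by -0.07), and the epithelial transcription factor ELF3 (by 1.93). The prostate transcription factor gene FOXA1 differed by 0.16 (adjusted p = 0.0513). Immediate early and AP-1 genes, which respond within minutes to growth signals, fell in 8 of 14 cases and rose in 2 (8 and 2 adjusted over the list alone), with a median of -0.78 and adjusted p = 0.0139 (adjusted p = 0.29 with an estimated correlation). IER2 fell by 0.71, DUSP1, a MAP kinase phosphatase gene, by 1.14, JUN by 1.05 and SPRY2, a feedback inhibitor of receptor kinases, by 0.84, and MYC rose by 0.55 (adjusted p = 0.0416).

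DNA replication genes of the G1/S transition were lower by small amounts: 19 of 30 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.27 and adjusted p = 0.00112 (adjusted p = 0.548 with an estimated correlation). The chromatin assembly gene CHAF1B fell by 0.55, E2F1 by 0.44 and the DNA polymerase gene POLA1 by 0.46. PPAR targets and fatty acid oxidation genes fell in 7 of 15 cases and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.26 and adjusted p = 0.041 (adjusted p = 0.29 with an estimated correlation). CPT1A, which admits fatty acids to mitochondria, fell 4.19-fold and ETFDH by 0.74 (adjusted p = 0.000659, or 0.0783 when centred on chromosomal neighbours; range over the alternatives 4.51e-05 to 0.0783), while the dehydrogenase gene ACADL rose by 1.03. The call of this list ended without parental replicate 2 (adjusted p = 0.0593) and without clone 2-96 (adjusted p = 0.0705), and with cyclic loess (0.0509), the deposited log2 values (0.0534) or the filter at all 8 arrays (0.0538), within a range of 2.16e-05 to 0.29 over the alternatives.

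Neighbours of NCOA6 on the long arm of chromosome 20 fell in 8 of 15 cases and rose in 1 (9 and 1 adjusted over the list alone), with a median of -0.31 and adjusted p = 0.0055 (adjusted p = 0.239 with an estimated correlation). PROCR, the protein C receptor gene, fell 24.3-fold, the autophagy gene MAP1LC3A by 2.25, EDEM2 by 0.75 and the ribosome factor gene EIF6 by 0.42. The median over 331 genes of chromosome 20 was -0.03.

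Ribosomal protein genes and chaperones of the endoplasmic reticulum rose. Of 35 cytosolic ribosomal protein genes 18 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.25 and adjusted p = 1.79e-05 (adjusted p = 0.664 with an estimated correlation). RPL30 rose by 0.59, RPL7 by 0.49, RPL32 by 0.43 and RPLP0 by 0.41. Shifts of whole chromosomes, described below, can add to the rise of single genes. Over the alternatives the smallest rises were 0.34 for RPL30, 0.22 for RPL7, 0.13 for RPL32 and 0.22 for RPLP0. When each gene was centred on its chromosomal neighbours, a setting chosen after the data were seen, RPL32 lost its call (adjusted p = 0.151, range over the alternatives 0.000308 to 0.151). The ribosomal list kept its call under that setting. Of 18 genes of the unfolded protein response 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.49 and adjusted p = 0.000429 (adjusted p = 0.639 with an estimated correlation). The co-chaperone gene DNAJB11 rose by 1.15, the chaperone gene HSP90B1 by 0.95, CRELD2 by 0.92 and SEL1L, a subunit of the degradation complex, by 0.89. The median of this list against wild type was 0.86 in clone 2-74, 0.66 in 2-96, 0.42 in 4-91 and 0.09 in 4-105.

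**Figure D2:**
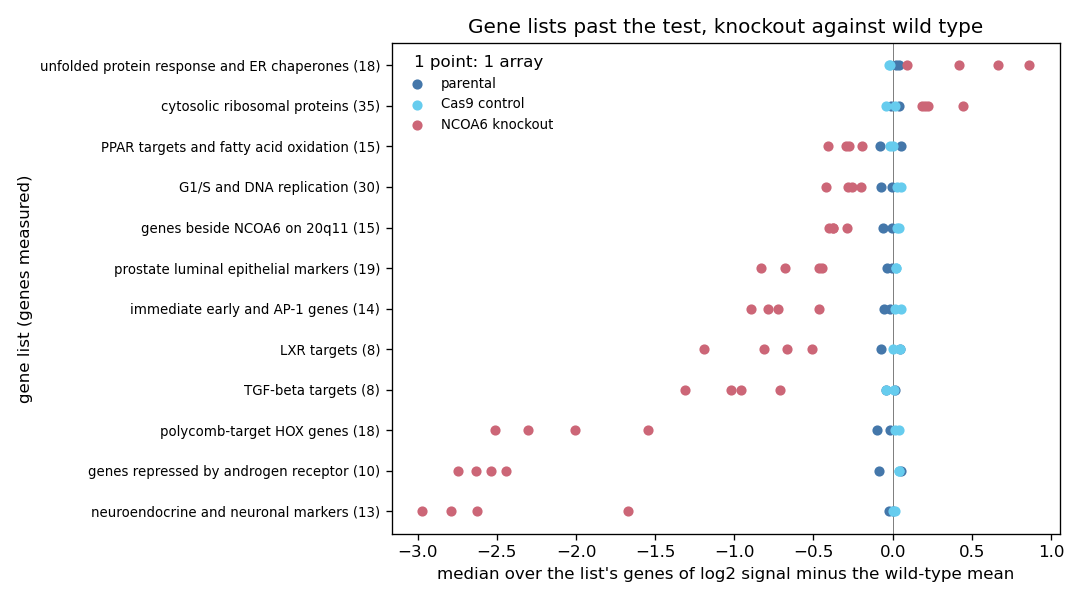
Median log2 difference from the wild-type mean (x axis) of the genes of each of the 12 gene lists (y axis) that passed the test between knockout and wild type, 1 point per array for all 8 arrays. The unfolded protein response list lay between 0.09 and 0.86 in the 4 clones.

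None of the 12 lists passed with an estimated correlation (0 of 39 lists). The estimated-correlation value was the highest adjusted p over the alternatives for each of the 12 except the neuroendocrine list. By fry, 24 lists moved one way on balance and 38 changed in either direction.

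Androgen-induced genes moved both ways and did not pass as a list: 10 of 34 rose and 7 fell (10 and 7 adjusted over the list alone; adjusted p = 0.541). SPOCK1 rose by 1.95, the lipid phosphatase gene PLPP1 by 1.57, PMEPA1 by 1.07, the glutamine transporter gene SLC38A2 by 1.03 and FKBP5, a chaperone of steroid receptors, by 0.61 (adjusted p = 0.00351). KLK3, which encodes prostate-specific antigen, differed by 0.24 (adjusted p = 0.622), KLK2 by 0.17 (adjusted p = 0.567) and TMPRSS2 by -1.18 (adjusted p = 0.114). On a further list, mostly of mitotic genes, members fell in 3 of 10 cases and rose in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.687): EDN2, MYBL2 and CCNA2 fell by 1.21, 0.48 and 0.39, and CENPF rose by 0.52. Among 15 other nuclear receptor coactivators and corepressors 2 rose and 3 fell (2 and 2 adjusted over the list alone; adjusted p = 0.836, median 0.00, mean -0.02). NCOA7 fell by 0.79 and CARM1 by 0.21, and NCOA1 rose by 0.38 and NCOA3 by 0.27. Of 9 subunits of the MLL3 and MLL4 complexes 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.806): the methyltransferase gene KMT2D rose by 0.48 and ASH2L by 0.32, and PAGR1 fell by 0.58 and PAXIP1 by 0.28.

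Metabolic lists also held changes in opposite directions. Of 22 cholesterol synthesis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.806), with a median of 0.10 and a mean of -0.06. TM7SF2 fell by 1.02. Fatty acid synthesis genes rose in 2 of 10 cases and fell in 3 (2 and 3 adjusted over the list alone; adjusted p = 0.782): the elongase gene ELOVL5 rose by 1.01 (its second probe by 2.04), ACSL3 rose by 0.82, and ACACB fell by 0.70 and ELOVL6 by 0.66. Glycolysis and hypoxia genes rose in 5 and fell in 8 of 25 cases (5 and 8 adjusted over the list alone; adjusted p = 0.782). The neuronal enolase gene ENO2 fell 10.4-fold and PDK1, which inhibits pyruvate dehydrogenase, rose by 0.74. The respiratory chain had 5 of 33 genes higher and 10 lower (5 and 11 adjusted over the list alone; adjusted p = 0.254), with NDUFS1 lower by 0.46 on the log2 scale (difference -0.46) and COX6C higher by 0.51. In the amino acid response driven by ATF4, 5 of 22 genes fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.225). The subunits of the leucine transporter, SLC7A5 and SLC3A2, fell by 3.59 and 2.32, and the stress factor gene DDIT3 rose 2.14-fold.

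Stress and growth lists that missed the threshold held single large changes. Targets of p53 fell in 8 of 21 cases and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.0543): the cell-cycle inhibitor gene CDKN1A was at least 3.01-fold lower, DDB2 fell by 0.99, FDXR by 0.87 and the death receptor gene FAS was at least 3.29-fold lower with 3 clones above background. NRF2 targets with the AKR1C genes fell in 7 of 16 cases and rose in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.0795), with AKR1C1 at least 15.5-fold lower beside AKR1C3. Metallothioneins, which bind zinc, fell in 4 of 10 cases and rose in 0 (6 and 1 adjusted over the list alone; adjusted p = 0.0727), among them MT2A (fell by 1.96, adjusted p = 0.018, or 0.11 with each wild-type line averaged first, the highest over the alternatives from 0.00151). Heat shock genes fell in 4 of 13 cases and rose in 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0924), with HSPB1 lower by a log2 difference of -0.61. Among G2/M genes 8 of 29 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.237), with the cytokinesis genes ANLN at -0.77 and PRC1 at -0.52. For MYC targets and ribosome biogenesis 6 of 22 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.529), with RRP9 at 0.68.

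Immune and signalling lists likewise did not pass. Interferon-stimulated genes fell in 8 of 18 cases and rose in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.0795). The RNA sensor gene IFIH1 was at least 4.33-fold lower and IFI6 rose by 1.98. Antigen presentation genes of MHC class I fell in 7 of 12 cases and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0957), with HLA-B 7.16-fold and the peptide transporter gene TAP1 3.24-fold lower. NF-kB genes fell in 4 of 7 cases and rose in 1 (4 and 2 adjusted over the list alone; adjusted p = 0.541, median -0.23, mean 0.07); IER3 rose 9.79-fold. WNT targets rose in 2 of 8 cases and fell in 2 (2 and 2 adjusted over the list alone; adjusted p = 0.997): RNF43, a ligase that removes WNT receptors, fell 15.0-fold and AXIN2 rose by 1.21. YAP and TEAD targets rose in 3 of 10 cases and fell in 2 (3 and 2 adjusted over the list alone; adjusted p = 0.754, median 0.16, mean -0.01): CCN1 fell 5.73-fold and F3, the tissue factor gene, rose 5.80-fold. NOTCH targets fell in 3 of 7 cases and rose in 1 (3 and 1 adjusted over the list alone; adjusted p = 0.225), and the receptor gene NOTCH3 was at least 60.8-fold lower with 3 clones above background. Retinoic acid targets had 1 of 5 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.529), and estrogen-induced genes 1 of 4 lower (1 adjusted over the list alone; adjusted p = 0.528).

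Markers of other cell states changed in both directions. Basal and squamous markers fell in 4 of 8 cases and rose in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.154): the laminin gene LAMB3 was at least 10.3-fold lower and KRT15 rose by 1.72. Mesenchymal genes rose in 5 of 12 cases and fell in 5 (5 and 5 adjusted over the list alone; adjusted p = 0.97, median 0.02, mean -0.15): the transcription factor gene SNAI2 rose 8.26-fold and the N-cadherin gene CDH2 was at least 11.3-fold lower, with a second CDH2 probe at -2.31. Cancer-testis antigens differed little, with 2 of 8 higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.836, median 0.02, mean -0.04); MAGEA4 fell by 0.52, and the probes of SSX2 disagreed in sign (0.28 and -0.06). Of 4 leukocyte markers above the filter 0 were called (0 adjusted over the list alone; adjusted p = 0.695; limma).

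Genes of the same chromosome shifted together in all 4 clones. Over 12094 genes above background on all arrays, the median difference from wild type was 0.34 on chromosome 3 (657 genes, 82.5% of them higher), 0.31 on chromosome 18 (163 genes, 84.0% higher) and 0.22 on chromosome 8 (422 genes). On chromosome 3 the clones lay between 0.33 and 0.37, whereas the medians of single wild-type arrays lay between -0.06 and 0.03 on all chromosomes. For 10 of 23 chromosomes the shift was beyond that of all 10000 random gene sets of the same size. Without genes of chromosomes 3, 8 and 18, a choice made after the data were seen, 7414 features were called between knockout and wild type.

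**Figure D3:**
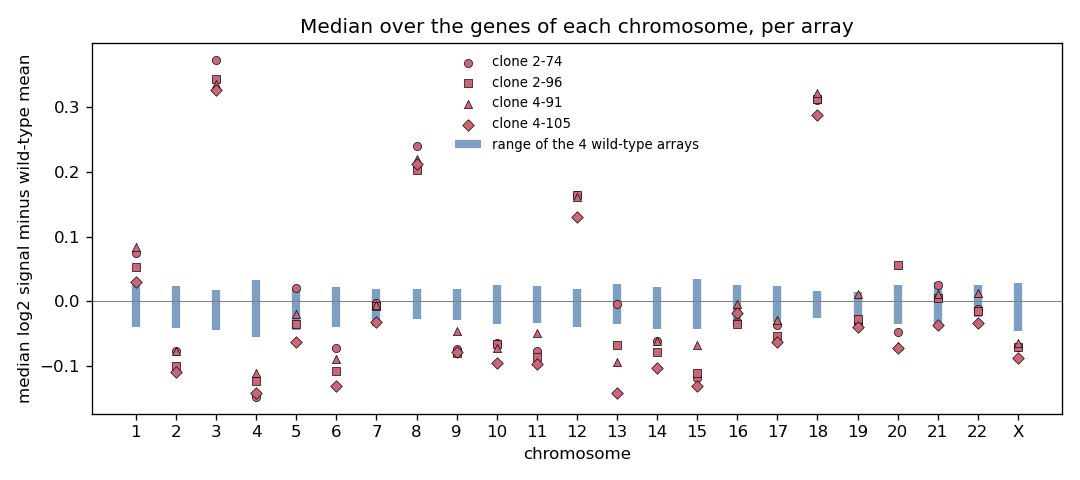
Median log2 difference from wild type (y axis) of the genes on each chromosome (x axis), with 1 point per knockout clone; the bar spans the medians of the 4 wild-type arrays. Chromosomes 3, 18 and 8 lay above 0.2 in each of the 4 clones, and the wild-type arrays lay between -0.06 and 0.03.

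Relative to the Cas9 control, APCDD1 (at least 10.4-fold), FLRT2 (at least 11.96-fold), CD83 (at least 4.93-fold) and FGF8, a growth factor gene (at least 9.09-fold), were higher and below background in the control, and VWA2 rose by 4.21 (SE 0.20, adjusted p = 2.87e-05). SPINK1 (at least 1272-fold), AKR1C3 (at least 251-fold), GULP1 (at least 99.96-fold) and VIL1 (at least 89.8-fold) were lower, and TSPAN8 was at least 198-fold lower with 1 clone above background. NCOA6 fell by 1.55 (SE 0.22, adjusted p = 0.00372). This control went through transfection and selection as the clones did. The comparison called 5885 features, 2779 higher and 3106 lower, and 11 of 39 lists. Leaving out Cas9 control replicate 1 or 2 left 2145 or 1952 calls.

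Relative to the parental line, FLRT2 (at least 12.9-fold), APCDD1 (at least 11.2-fold), CNTN3 (at least 7.22-fold) and CD83 (at least 5.30-fold) were higher and below background in the parental cells, and CPS1 rose by 3.93 (SE 0.18, adjusted p = 2.54e-05). SPINK1 (at least 1249-fold), AKR1C3 (at least 263-fold), GULP1 (at least 94.9-fold) and VIL1 (at least 87.0-fold) were lower, TSPAN8 was at least 172-fold lower and NCOA6 fell by 1.48 (SE 0.22, adjusted p = 0.00446). In total 5665 features were called, 2894 higher and 2771 lower, and 12 of 39 lists. Without parental replicate 1 or 2 the count was 2202 or 2561. No list of either comparison passed with an estimated correlation (0 of 39).

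No named gene was called between the Cas9 control and the parental line. The smallest p-values belonged to the glycerol channel gene AQP9 (at least 1.44-fold lower in the control, adjusted p = 0.146), FGF8 (at least 1.28-fold lower, adjusted p = 0.201) and SPEG (difference -0.90, adjusted p = 0.206). By limma 2 features passed, both lower and below background in the control, and both probes without a gene name, A_33_P3283734 and A_21_P0014468 (adjusted p = 0.00301 each). At an unadjusted p under 0.05 there were 415. Replicates of both lines did not overlap for 34.7% of features, where chance gives 33.3%. Lists of G1/S genes (median 0.08, adjusted p = 0.0171), MYC targets (0.07, adjusted p = 0.028) and the respiratory chain (0.06, adjusted p = 0.028) were called higher by the preset test with 0 members called over all genes or adjusted over the list alone (limma). With an estimated correlation adjusted p = 0.999 for each, the highest over their alternatives (lowest 0.00128, 0.00385 and 0.00156). Quantile normalization (adjusted p = 0.064 for each), cyclic loess, the deposited log2 values, no filter and fry ended all 3 calls. So did leaving out parental replicate 1 (0.978 for each), Cas9 control replicate 1 (0.051, 0.0889 and 0.147) and Cas9 control replicate 2 (0.285, 0.561 and 0.285). The MYC list also lost its call without parental replicate 2 (0.164), and the MYC and respiratory lists without clone 2-96 (0.0511), 4-91 (0.0547) or 4-105 (0.0564). Without Cas9 control replicate 1 or 2 the test called 0 single features (limma; 431 and 341 at an unadjusted p under 0.05).

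A replicate block was tried for this comparison on the 4 wild-type arrays alone. With the replicate number as a block 0 features were called (limma; 1120 at an unadjusted p under 0.05), and without the block 0 (914 unadjusted).

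Few features were called between the clones of series 4 and those of series 2. LAT2, an adaptor of immune receptors, was 7.42-fold higher in series 4 (2.37 ± 0.22 against -0.52 ± 0.21, SD, n = 2 each, adjusted p = 0.000602). NPTX1, a neuronal pentraxin gene (at least 5.53-fold), STMN2, a neuronal microtubule regulator gene (at least 2.00-fold), TRIM48 (at least 1.83-fold) and MYO1A (at least 1.63-fold) were higher in series 4 and below background in series 2. TINAG (at least 2.18-fold), BCAT1, a branched-chain aminotransferase gene (at least 1.96-fold), FSIP2 (at least 1.74-fold), ODAM (at least 1.44-fold) and PLP2 (at least 1.32-fold) were lower and below background in series 4. In all 56 features were called, 21 higher and 35 lower in series 4 (2094 at an unadjusted p under 0.05), and clones of both series did not overlap for 34.0% of features, where chance gives 33.3%. The count rested on the spread shared with the wild-type arrays: on the 4 knockout arrays alone it was 0 (limma; 926 unadjusted). It was 26 without parental replicate 1, 29 without parental replicate 2, 28 and 29 without Cas9 control replicate 1 and 2, 183 without clone 2-74, 852 without 2-96, 267 without 4-91 and 167 without 4-105.

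Calls of 4 of these 10 genes depended on single arrays. Without parental replicate 1, parental replicate 2, Cas9 control replicate 1 or Cas9 control replicate 2, the adjusted p was 0.118, 0.103, 0.112 or 0.1003 for STMN2, 0.0646, 0.0573, 0.0586 or 0.0573 for MYO1A, and 0.0934, 0.0949, 0.0928 or 0.0775 for ODAM. For TRIM48 it was 0.0636 or 0.067 without Cas9 control replicate 1 or 2, and for STMN2 0.055 without clone 2-74. Over all alternatives the adjusted p lay between 0.00118 and 0.8 for STMN2, between 0.00052 and 0.704 for MYO1A, between 0.00335 and 0.8 for ODAM and between 0.00249 and 0.383 for TRIM48.

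As lists, endoplasmic reticulum chaperones (median -0.47, adjusted p = 1.19e-09), cholesterol synthesis genes (-0.27, adjusted p = 3.19e-07) and ribosomal protein genes (-0.12, adjusted p = 0.00123) were called lower in series 4 than in series 2. Metallothioneins (0.91, or 0.83 with 1 member at its bound, adjusted p = 4.02e-05), G1/S genes (0.12, adjusted p = 0.0169) and NOTCH targets (0.64, adjusted p = 0.0311) were called higher. No member of the 6 lists was called over all genes (0; limma), and adjusted over the list alone the counts were 13 chaperones and 6 cholesterol genes lower, 2 metallothioneins higher, 3 NOTCH genes higher and 1 lower, and 0 ribosomal and 0 G1/S genes. With an estimated correlation adjusted p = 0.432 for chaperones, cholesterol genes, metallothioneins and NOTCH targets, adjusted p = 0.74 for ribosomal and adjusted p = 0.707 for G1/S genes. The chaperone gene HSPA5 had a difference of -1.03 (adjusted p = 0.109), HERPUD1 -1.01 (adjusted p = 0.0803), the sterol synthesis gene HSD17B7 -0.73 (adjusted p = 0.181) and MT1F 1.28 (adjusted p = 0.0675). Leaving out clone 2-74 ended the calls of ribosomal (adjusted p = 0.878), G1/S (0.514) and NOTCH genes (0.0605), clone 4-91 those of ribosomal and NOTCH genes (0.146 each), and clone 4-105 those of G1/S (0.329) and NOTCH genes (0.0844). Quantile normalization ended the ribosomal and NOTCH calls (0.404 and 0.0606), and fry all but the NOTCH call. The medians also moved with single arrays: over the 8 arrays left out in turn they ranged from 0.24 to 1.47 for metallothioneins, 0.19 to 1.13 for NOTCH targets and 0.054 to 0.155 for G1/S genes, lowest without clone 2-74 and highest without clone 2-96. Chaperones ranged from -0.64 to -0.31, cholesterol genes from -0.34 to -0.17 and ribosomal genes from -0.26 to 0.027. The NOTCH median was 0.149 with normexp background (adjusted p = 0.191) and 0.021 with the filter at all 8 arrays (adjusted p = 0.843). Over all alternatives the highest adjusted p was 0.878 for ribosomal, 0.843 for NOTCH, 0.707 for G1/S and 0.432 for the other 3 lists.

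In series 2 against wild type, APCDD1 (at least 14.9-fold), EDNRA (at least 7.88-fold), CD83 (at least 7.66-fold) and FLRT2 (at least 10.4-fold) were higher, and VWA2 rose by 4.17, while SPINK1 (at least 1236-fold), AKR1C3 (at least 252-fold), MYO1A (at least 98.7-fold), VIL1 (at least 86.6-fold) and KLK11 (at least 80.1-fold) were lower. In series 4 against wild type, FLRT2 (at least 14.8-fold), CNTN3 (at least 8.35-fold), APCDD1 (at least 7.83-fold) and CD83 (at least 3.41-fold) were higher, and the guidance gene SEMA3D rose by 4.18, while SPINK1 (at least 1286-fold), TSPAN8 (at least 322-fold), AKR1C3 (at least 262-fold), AMER3 (at least 206-fold) and VIL1 (at least 90.1-fold) were lower. NCOA6 fell by 1.56 in series 2 and by 1.47 in series 4 (adjusted p = 0.00238 and 0.00329). Series 2 against wild type called 7258 features (3618 higher, 3640 lower) and 13 lists, and series 4 against wild type 6501 (3086 higher, 3415 lower) and 12 lists. With an estimated correlation 0 lists passed in either.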

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

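Single clones lay far from the other clones for 3 of 55 named genes, by the gap to the nearest clone divided by the whole range, where chance gives about 1 in 20 (2.75 of 55). Another 17 named genes, with no clone above background, were left out after their values were seen, since such values have no order. The endothelin receptor gene EDNRA was below background in clone 4-105 (-4.77), whereas the other clones lay between -0.56 and 0.18, a gap of 0.851 of the range. With clones below background held at the lowest measured level, the gap of EDNRA was 0.732, under the limit for a flag, and those of TSPAN8 and KLK11, each above background in 1 clone, passed it: 0.948 for clone 2-74 (from 0.669) and 0.852 for clone 4-91 (from 0.649). ID2, an inhibitor of helix-loop-helix factors, was lower in clone 4-105 (1.06) than in the other clones (3.08 to 3.25), a gap of 0.924. MET lay at -1.45 in clone 2-74 and between -1.12 and -1.09 in the others, a gap of 0.914.

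The clone series differed in their change from wild type for 10 named genes, by the limma test of series 4 against series 2. The genes were named as the largest changes of this same test, so the flag repeats that choice. Of the 72 genes named for knockout against wild type as largest changes, as the target or from lists that passed there, 1 (MYO1A) was called between the series. The differences were 3.02 for TRIM48, 2.90 for STMN2, 2.89 for LAT2, 2.63 for NPTX1 and 2.37 for MYO1A, all higher in series 4, and -3.21 for TINAG, -2.84 for FSIP2, -2.51 for PLP2, -2.47 for ODAM and -2.39 for BCAT1, all lower in series 4. For all but LAT2, 1 of the series was below background, so these fitted differences are not bounds. Each series held 2 clones, and a difference between series is also a difference between those clones. No biological explanation was tested.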

How the results depend on the processing

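Between knockout and wild type the calls held under most of the settings tried, and the counts moved with the filter, the threshold and the number of wild-type units. Centring on chromosomal neighbours and leaving out chromosomes were chosen after the data were seen. Of 91 named genes, 76 kept direction and call under every setting (2093 of 2130 values), and 37 values lost the call with the same direction. The 12 lists kept theirs in 305 of 324 values. Signal over background limits the dim genes: bounds, not folds, are known for genes below background. The comparisons knockout versus wild type, clone series 2 versus wild type and clone series 4 versus wild type rose to 22224 calls (80.5% higher in the clones), 20162 (81.8%) and 14900 (78.2%) without a filter on dim probes, knockout versus parental to 18423 (83.0%), knockout versus Cas9 control fell to 3602 (45.4%), and gene lists called rose to 24. The all-gene median was then 0.35 in knockout versus wild type. Subtracting the 75th percentile places a probe without signal higher on a dimmer array. That percentile was 77.5 to 82.6 on knockout arrays and 85.5 to 102 on wild-type arrays. Many of these calls therefore need not be changes of expression, and the share that scaling accounts for was not tested. For knockout versus wild type, 4894 were called with wild-type lines averaged, 2321 at a fitted difference of 2-fold or more and 5243 at an adjusted p under 0.01, by fewer samples or a stricter limit. The gene lists called were 19 with normexp background, 24 with fry and 0 with an estimated correlation (range 0 to 24 over the settings); for normexp and fry the cause was not tested.

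The comparison Cas9 control versus parental called 0 by limma with normexp (321 at an unadjusted p under 0.05), the series values (280), filters at 4 arrays (331) or all 8 arrays (249) and a trended prior (237), and 7 with array weights (962). With the replicate block it called 0 (1120 unadjusted), and on the 4 wild-type arrays without the block 0 (914). The comparison clone series 4 versus clone series 2 called 20 with the filter at 4 arrays, 4 at all 8 arrays, 24 with array weights and 0 on the 4 knockout arrays alone (926 unadjusted; fewer samples). For the others the cause was not tested.

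Leaving out 1 array gave 6727 to 8394 calls for knockout versus wild type, -1.68 to -1.38 for NCOA6 and 11 to 17 lists. For knockout versus Cas9 control it gave 1952 to 6228 (2145 without Cas9 control replicate 1, 1952 without replicate 2), and for knockout versus parental 2202 to 6034 (2202 without parental replicate 1, 2561 without replicate 2), where the lone wild-type array is assumed to vary like the other groups. Cas9 control versus parental gave 0 to 3 (0 without either control replicate; limma). Clone series 4 versus clone series 2 gave 26 to 852: 26 and 29 without parental replicate 1 and 2, 28 and 29 without Cas9 control replicate 1 and 2, 183 without clone 2-74, 852 without 2-96, 267 without 4-91 and 167 without 4-105. Clone series 2 versus wild type gave 5502 to 7472 and clone series 4 versus wild type 4453 to 7471. The ribosomal list between the series lay between -0.26 and 0.027, and without clone 2-74 its direction reversed (0.027, adjusted p = 0.878; range over the settings 4.85e-08 to 0.878). The cause was not tested.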

Other observations

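The tests of the chromosome pattern, of a separate cell population and of another cell line were chosen after the result was seen; those of chance splits, of the slide row and of the liver and gut list were written before, although levels of other liver and gut genes had been seen.

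Genes of liver and gut epithelium were measured in 22Rv1 and mostly fell in the clones. ALB, which encodes serum albumin, fell from 7.60 ± 0.05 to 1.17 ± 0.82 (SD, n = 4 each, adjusted p = 1.08e-05). HNF4G, a nuclear receptor of gut epithelium, differed by -0.37 (adjusted p = 0.144). The bile acid receptor gene NR1H4 was at least 1.62-fold lower and GATA6, a gut transcription factor, fell by 1.27, while NR5A2, a regulator of liver genes, rose by 1.36. Below background in all 4 clones were the organic anion pump gene ABCC2 (at least 7.04-fold lower), CLRN3 (at least 4.64-fold), the membrane protease gene TMPRSS4 (at least 4.56-fold), the phosphate transporter gene SLC17A4 (at least 4.54-fold), the glucuronidation gene UGT1A6 (at least 3.17-fold), the vitamin D-binding protein gene GC (at least 1.34-fold) and CEACAM6 (at least 1.08-fold). TTR, which encodes transthyretin, was at least 11.6-fold lower with 1 clone above background, and APOM rose by 0.68. CPS1, whose urea cycle enzyme is also typical of liver, went the other way and was among the largest rises given above.

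Of the features tested, 510 were above background on all wild-type arrays and on none of the clones for any probe (324 protein-coding; 59 at least 8-fold lower). The reverse held for 49 features (31 protein-coding; 4 at least 8-fold higher). Knockout arrays were dimmer, with a 75th percentile of 77.5 to 82.6 against 85.5 to 102 in wild type. Features near background could therefore drop out more easily in the clones, and the 2 counts are not on equal terms. On simulated changes the same procedure recovered 72 of 100 at 2-fold and 86 of 100 at 4-fold between knockout and wild type, with 15 false calls among 173. Between Cas9 control and parental it recovered 46 of 100 at 2-fold and 76 of 100 at 4-fold. Between the clone series it recovered 54 and 84 of 100. Few calls in these comparisons of 2 against 2 arrays therefore need not mean few differences. The simulation changed 200 of 19858 genes and drew independent arrays with the same spread in both groups. The real data had 42.4% of features called and a wider spread among clones, so these rates need not hold for them.

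Many genes differed between the 4 knockout clones and the 4 wild-type arrays. Of the 35 ways to split the 8 arrays into 4 and 4, only the real split, 1 of 35, gave as many calls (8413, and the highest other gave 0). Every other split mixed clones with wild-type arrays in each group, which puts the difference into the spread. The splits therefore show that the arrays divided along the genotype labels. They cannot tell an effect of NCOA6 from any other difference along those labels. Spike-in RNAs, added in the same amounts to each array, differed between the slide rows with an SD of 0.0245 over 7 spike-ins. Over 15832 genes the SD was 0.601, a ratio of 0.0408 (upper bootstrap limit 0.0535, from only 7 values). Each spike-in was a mean over 35 spots and most genes rest on fewer, so the ratio is lower than for like values. The small SD argues against a row effect shared by all spots of a probe as the cause of the bulk of the differences. Differences in culture or RNA handling before the spike-ins were added would not show in them. What stays open is that spread between clones picked as single cells and the loss of NCOA6 come together in each clone, and the labels do not say whether the control line was cloned.

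Genes on chromosomes 3, 8 and 18 were higher in all 4 clones. On chromosome 3 the lower quartile of genes moved as far as the median (ratio 1.03, bootstrap 0.917 to 1.12), which argues against regulation of a few genes there. Profiles of 473 windows of 25 genes correlated between clones with r of at least 0.802 across windows, each clone set against a different wild-type line. Any expression change shared by the clones also raises this r, so r alone does not test separate random changes in each clone. The clones' medians were alike on chromosomes 3 (0.33 to 0.37), 8 (0.20 to 0.24) and 18 (0.29 to 0.32). This argues against separate random changes as the source of these 3 shifts. A gain of these chromosomes in a shared ancestor of the clones may account for the pattern; so might selection of the same gains after loss of NCOA6, and the lowest correlation between the series, also 0.802, leaves both open because either predicts it. DNA copy number was not measured.

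Most measured liver and gut genes were lower in the clones, and a candidate explanation is lower activity of a shared liver and gut expression program. Of 50 textbook liver and gut genes whose values had not been looked at, 14 were measured, 11 of them lower, 1 higher and 2 not called. The median was -2.41, or -1.25 with 8 members at their bounds (camera p = 9.86e-07, p = 0.00355 with an estimated correlation). Lower activity of such a program would give this direction. However, 7 members below background in all 4 clones passed the filter through the wild-type arrays alone, so they could only be lower. PKLR, below background in wild type, could only be higher. Above background on all 8 arrays, EPS8L3 differed by -1.14, SERPINA6 by -0.17 (not called) and APOM by 0.68. The list test is therefore weak evidence for such a program, and what drives these genes in 22Rv1 was not measured. Another cell line under the knockout label would be likely to differ in cancer-testis antigens, but the largest difference among 8 of them was 0.516 (MAGEA4), which argues against an unrelated line and leaves a related stock open. A separate liver-like population in the wild-type cultures, lost on cloning, would raise prostate genes in the clones; the luminal list had a median of -0.55 (bootstrap -1.30 to 0.09 over 19 members), so this stays open. Loss of NCOA6 and outgrowth of cells in which this program was already low are both possible and were not told apart by these arrays.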
